A study of Sus scrofa with 22 samples.

How the data were processed

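The samples were cerebella of 22 newborn piglets (Sus scrofa) that had bile duct ligation (BDL), which blocks the flow of bile out of the liver, or sham surgery (SHAM) at day 8 of life and were followed for 3 weeks. Total RNA was extracted with a column kit made for fatty tissue and sequenced as 150 bp read pairs on an Illumina NovaSeq, per the labels' protocols. The labels give the treatment, the sex and a body weight of each animal. The unit of the weight and the age at weighing are not given in the sources used here, so weights are printed without a unit.

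The deposited values are whole-number read counts per Ensembl gene, 1 table per animal, with no normalization. The submitters' processing notes name Trim Galore for read trimming, HISAT2, HTSeq and DESeq2, and the pig genome build Sscrofa11.1. Versions, the strand setting of the counting and the submitters' own statistical model are not given in the sources used here. If the counting ignored strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical gene copies may have been left out as not uniquely placed. Each table ends with 5 lines that belong to no gene, which held between 29.9% and 34.6% of the counted reads. They were kept out of the library sizes and of every test.

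The tables hold 31907 gene identifiers, of which 15029 were matched to a symbol and 16878 were not. Unmatched identifiers were tested and are reported as counts. Chromosome positions were taken by symbol from a RefSeq gene table of the same build, Sscrofa11.1. Total gene counts ran from 14811464 to 20046909 per library, and between 19538 and 20490 genes had at least 1 count. No pair of libraries looked like the same library deposited more than once: over the 231 pairs, the chi-square per degree of freedom of their counts lay between 6.82 and 48.2. The replicate numbers follow the order of deposition and pair no animals. Whether animals shared a litter is not given in the sources used here.

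Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3) with treatment as the group, a minimum count of 10 and a minimum total of 15, which left 14994 genes, 12317 of them with a symbol. Counts were scaled by TMM. The test of BDL against SHAM was edgeR's quasi-likelihood test with a robust fit on sex and treatment. The female against male comparison came from the same fit. The interaction of treatment and sex and the effects within each sex came from a model of the 4 groups, so that all 22 animals share 1 estimate of the spread. The association with body weight was tested per standard deviation of weight, beside sex and treatment. A gene counted as changed when its Benjamini-Hochberg adjusted p was under 0.05. Log2 fold changes are given with standard errors, and intervals are at 95% confidence.

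Before the data were examined, 44 gene lists were fixed from textbook knowledge of cholestasis, lipid metabolism, stress responses and cerebellar cell types. Of these, 42 had at least 5 measured members. Two-sided camera tests (limma 3.58.1) on log2 CPM with a prior count of 2 used a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and the fry test stand beside them. A score per animal, the mean log2 CPM of a list's members, was compared by a two-sided permutation test of treatment within sex with 100000 resamples. The brainstem and deep nuclei markers, with 3 measured members, and the genes specific to 1 sex, with 0 measured members after the count filter, were not tested as lists.

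The genes named in the text follow a rule fixed in advance: the 5 genes with the smallest p on each side of the treatment comparison as values when none pass, up to 2 members with the smallest p of each list that has no changed member, up to 4 genes for each other contrast, and 12 genes named whatever their values. Some genes that the rule names are not reported here. Other genes that are named were chosen after their values were seen, and the text says so.

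The gene test was checked on simulated counts drawn from these libraries' means, sizes and dispersions over 14994 genes, in 5 runs of BDL against SHAM. Each run drew the genes independently and changed 67 by 1.25-fold, 67 by 1.5-fold and 66 by 2-fold. The test recovered 45.1% of genes changed 1.25-fold, 72.8% of those changed 1.5-fold and 89.7% of those changed 2-fold. A mean of 4.4 false calls stood among 142.6 calls. The adjusted threshold is easier to pass when many genes change, so recovery would be lower where few genes do. On 200 simulated lists of 20 correlated genes with no treatment effect, camera with the preset correlation gave an unadjusted p under 0.05 for 61% of lists, camera with an estimated correlation for 7.5% and the score test for 4%. In these lists the part shared by the genes varied as much as their own noise. That is more correlation than was estimated for the real synapse (0.10) and immediate early gene (0.37) lists, and less than for the interferon list (0.74). The 61% is therefore not a rate for the real lists.

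The alternatives tried were RLE and upper-quartile scaling, no filter beyond a total count above 0, a filter of at least 1 CPM in at least 11 libraries, limma-voom with sample quality weights, DESeq2 1.42.0 on all genes with a count and on the genes of the count filter (not for body weight), other covariates including 3 surrogate variables from sva 3.50.0, a non-robust fit, an adjusted p under 0.1, a test against a 1.2-fold change, and leaving out each animal in turn. Treatment labels were regrouped within sex, and sex labels within treatment, in 100 splits each, the real split included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.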

Results

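RNA of the cerebellum, the brain region that coordinates balance and movement, was counted per gene in 11 BDL piglets (7 female, 4 male) and 11 SHAM piglets (5 female, 6 male). Libraries held between 14811464 and 20046909 gene counts. The labelled body weight was 2044 ± 313 in BDL and 2035 ± 273 in SHAM animals (mean ± SD, n = 11 each; two-sided permutation p = 0.954, and 0.815 within sex). The exact permutation p was 0.918 within females (7 and 5 animals) and 0.771 within males (4 and 6 animals). Sex labels fitted the sex-linked genes in 22 of 22 libraries: KDM5D, a histone demethylase gene of the Y chromosome, had 0 to 2 counts in females and 234 to 355 in males. EIF1AY, a Y-linked translation factor gene, had 0 to 2 counts in females and 445 to 897 in males.

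The comparison of BDL with SHAM asks which cerebellar transcripts change when bile flow is blocked early in life. No gene passed the test. The genes with the smallest p on the higher side were TPD52L1, a tumor protein D52 family member (chromosome 1, 37667476 to 37761670 on Sscrofa11.1), with 3.70 ± 1.41 CPM in BDL and 2.46 ± 0.57 in SHAM (log2 fold change 0.66 ± 0.14 SE, higher than the SHAM mean in 8 of 11 BDL animals, adjusted p = 0.822), and GPRC5C, an orphan G protein-coupled receptor (0.26 ± 0.07). RAB33A, a small GTPase of vesicle traffic, was at 0.21 ± 0.05, MEIOC, a meiosis gene, at 0.80 ± 0.21 and RASGEF1A at 0.21 ± 0.06. On the lower side stood MYOM1, which encodes a sarcomere protein (-0.41 ± 0.10), and HR, a thyroid hormone-responsive corepressor gene (33.0 ± 9.1 CPM in BDL and 40.3 ± 9.1 in SHAM, -0.42 ± 0.10, adjusted p = 0.881). PLCB1, a phospholipase C gene of receptor signalling, was at -0.29 ± 0.08, TBC1D32 at -0.29 ± 0.08 and CNR1, the CB1 cannabinoid receptor gene, at -0.25 ± 0.07, below the SHAM mean in 11 of 11 BDL animals.

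edgeR's quasi-likelihood test called 0 of 14994 genes at an adjusted p under 0.05, with 744 at an unadjusted p under 0.05 where 750 would be expected by chance and a smallest adjusted p of 0.822. limma-voom called 0, with 924 at an unadjusted p under 0.05. DESeq2, run without the count filter on 25709 genes, called 1, TPD52L1 (adjusted p = 0.0398), with 961 at an unadjusted p under 0.05. On the 14994 filtered genes it called 1, again TPD52L1 (adjusted p = 0.0410), with 769. The 95% confidence interval of the change lay inside 1.25-fold in either direction for 63.6% of genes, inside 1.5-fold for 87.1% and inside 2-fold for 98.1%.

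Genes of sterol and bile acid handling did not pass the test. CYP7A1, the rate-limiting enzyme of hepatic bile acid synthesis, had 11 counts over all 22 libraries and no fold change is given. CYP27A1, which makes 27-hydroxycholesterol, was at 33.0 ± 5.5 CPM in BDL and 31.6 ± 8.1 in SHAM (log2 fold change 0.02 ± 0.12), and CYP46A1, the neuronal cholesterol 24-hydroxylase, at 51.6 ± 5.0 and 49.7 ± 7.2 (0.04 ± 0.07). Of the cholesterol synthesis list, 18 of 22 members were on the higher side (median 0.08, camera adjusted p = 0.0767), with EBP at 0.15 ± 0.07 and TM7SF2 at 0.19 ± 0.09. Among bile acid receptors and transporters 6 of 8 members were higher (median 0.09, adjusted p = 0.214), with KLB, the FGF19 co-receptor gene, at 0.29 ± 0.10 and SLCO1A2, an organic anion transporter gene, at 0.18 ± 0.11. Oxysterol and bile acid enzymes (5 of 8 higher, adjusted p = 0.992) included CYP7B1 at -0.25 ± 0.19 and SLC27A5 at 0.17 ± 0.24. LXR targets and sterol efflux genes split 6 and 6 (adjusted p = 0.957), with SREBF1 at 0.12 ± 0.10 and ABCG4 at -0.06 ± 0.05.

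Fatty acid and membrane lipid genes did not pass either. FADS2, the delta-6 desaturase, was at 305 ± 26 CPM in BDL and 293 ± 20 in SHAM (0.06 ± 0.05), ELOVL5, a fatty acid elongase, at 67.5 ± 13.4 and 67.2 ± 8.0 (0.01 ± 0.10), and MFSD2A, which carries docosahexaenoic acid across the blood-brain barrier, at 15.5 ± 3.0 and 14.2 ± 2.9 (0.10 ± 0.12). Fatty acid synthesis, elongation and desaturation genes split 9 higher and 10 lower (camera adjusted p = 0.992; ELOVL1 0.23 ± 0.16, MECR 0.06 ± 0.04). Of the fatty acid transport and binding list 4 of 15 members were higher (adjusted p = 0.850; FABP7 0.12 ± 0.06, ACSL6 -0.08 ± 0.05). Phospholipid synthesis and remodelling had 15 of 28 higher (adjusted p = 0.782; PTDSS2 0.10 ± 0.06, PCYT1B -0.09 ± 0.06). Sphingolipid and ganglioside metabolism had 19 of 32 higher (adjusted p = 0.850), with ST8SIA1, the GD3 synthase gene, at -0.15 ± 0.07 and UGCG, the glucosylceramide synthase gene, at -0.20 ± 0.10. Fatty acid oxidation, ketone and PPAR targets split 10 and 10 (adjusted p = 0.693; OXCT1 -0.19 ± 0.07).

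**Figure D1:**
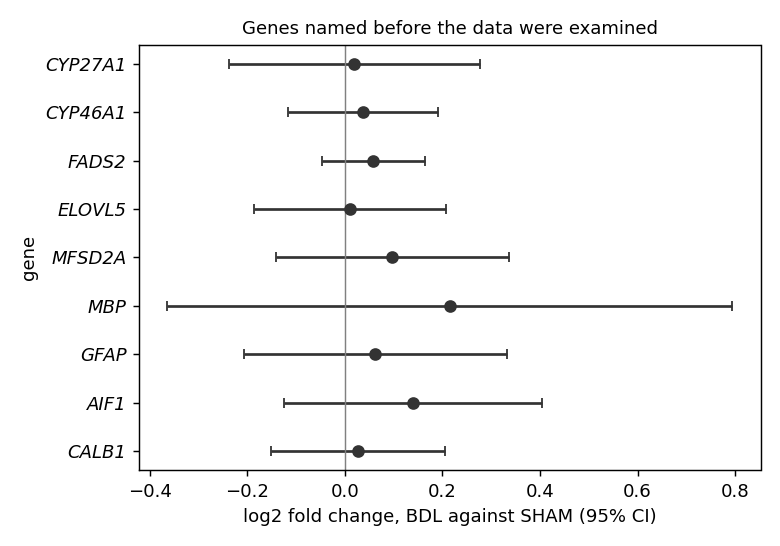
Log2 fold change of BDL against SHAM (points) with 95% confidence intervals (bars) for 9 genes chosen before the data were examined, n = 11 animals per group. Every interval contains 0; the widest is that of MBP, from -0.36 to 0.79.

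Camera with the preset correlation placed 3 of 42 lists apart from the other genes, and none of the 3 calls held with an estimated correlation. The number of lists was 7 without BDL replicate 2 or SHAM replicate 5, 6 without BDL replicate 4 or 10 or SHAM replicate 3, 7 or 11, 5 without BDL replicate 7, 8 or 11 or SHAM replicate 4, and 1 without SHAM replicate 6. All 26 measured interferon response genes, which are switched on by antiviral signalling, were on the higher side in BDL (median log2 fold change 0.31, camera adjusted p = 3.65e-08; adjusted p = 0.842 with an estimated correlation). The examples with the smallest p were IRF7, an interferon regulatory factor (0.56 ± 0.23, 14.9 ± 6.3 CPM in BDL and 9.54 ± 4.02 in SHAM), and USP18, which removes ISG15 from proteins (0.86 ± 0.36). The list's mean log2 CPM was 4.15 ± 0.62 in BDL and 3.67 ± 0.67 in SHAM, above the SHAM mean in 9 of 11 BDL animals (permutation p within sex = 0.150, adjusted p = 0.931). Markers of blood cells stood beside it, with 5 of 6 members higher and a score difference of 0.37 (p = 0.0449, adjusted p = 0.475; camera adjusted p = 0.242; CD2 0.46 ± 0.42, HBB 0.44 ± 0.47). Their mean log2 CPM was low, at 1.19 ± 0.49 in BDL and 0.76 ± 0.35 in SHAM. The blood cell difference was 0.67 in females and -0.0007 in males (permutation p of the difference between the sexes 0.0499, adjusted 0.527). The interferon difference was 0.53 in females and 0.27 in males. Of the interferon list, 0 members passed adjusted over the list alone and 0 over all genes.

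Immediate early genes, which neurons switch on within minutes of activity, had 15 of 17 members on the higher side (median 0.17, camera adjusted p = 0.00384; adjusted p = 0.842 with an estimated correlation). EGR1 was at 0.37 ± 0.16 and KLF2 at 0.27 ± 0.13, and the score was 3.30 ± 0.31 in BDL against 3.03 ± 0.47 in SHAM (permutation p = 0.194, adjusted p = 0.931), above the SHAM mean in 8 of 11. The score difference was 0.43 in females and 0.01 in males, where 1 of 4 BDL animals was above the male SHAM mean (permutation p of the difference between the sexes 0.264, adjusted 0.828). The camera adjusted p was 0.0560 without BDL replicate 3, 0.0565 without SHAM replicate 6 and 0.125 without SHAM replicate 8. Glutamatergic and GABAergic synapse genes had 23 of 28 members on the lower side by a small amount (median -0.05, camera adjusted p = 0.0284; adjusted p = 0.842 with an estimated correlation), with GRIN2A, an NMDA receptor subunit, at -0.44 ± 0.17 and GABRA6, the granule cell GABA-A subunit, at -0.10 ± 0.05. Their score was 7.54 ± 0.07 against 7.61 ± 0.07 (permutation p = 0.0453, adjusted p = 0.475; lower than the SHAM mean in 9 of 11). That camera adjusted p was 0.0517 without BDL replicate 1, 0.0862 without SHAM replicate 1, 0.0682 without BDL replicate 5, 0.0655 without BDL replicate 6, 0.0565 without SHAM replicate 6 and 0.0729 without SHAM replicate 8. Over 30 alternatives the synapse call was lost in 9, including these 6 without 1 animal.

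**Figure D2:**
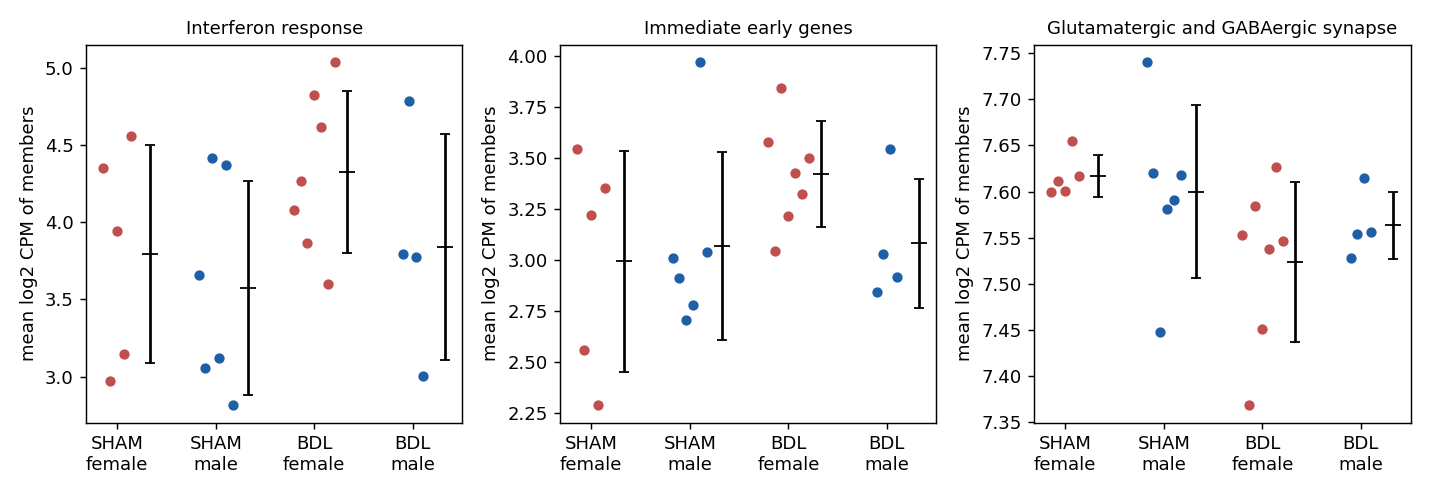
Mean log2 CPM of the members of 3 lists in each animal (points), by treatment and sex, with the group mean ± SD (bars; n = 5, 6, 7 and 4 from left to right). The BDL and SHAM animals overlap in each list, and the interferon score ranges from 2.81 to 5.04 over the 22 animals.

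The other cell type lists did not pass camera. Granule neuron markers had 13 of 18 members lower (adjusted p = 0.0640), and their score lay below the SHAM mean of both sexes in 11 of 11 BDL animals (score difference -0.07, permutation p = 0.0392, adjusted p = 0.475). The difference was -0.10 in females and -0.04 in males (unadjusted permutation p = 0.0156 and 0.516), where 1 of 4 BDL animals was above the male SHAM mean. GABRA6, GABRD, GRM4 and SLC17A7 are also in the synapse list, so the lower values of these lists are not independent. KCND2, a potassium channel gene, was at -0.27 ± 0.11 and CALB2 at -0.32 ± 0.13. Purkinje cell markers split 12 higher and 9 lower (adjusted p = 0.908), with CALB1 at 389 ± 71 and 390 ± 53 CPM (0.03 ± 0.09), PLCB4 at -0.16 ± 0.05 and PCP2 at 0.15 ± 0.08. Granule cell precursor (11 of 17 higher, adjusted p = 0.957; PTCH1 -0.12 ± 0.07) and cerebellar interneuron markers (9 of 16 higher, adjusted p = 0.850; TFAP2A -0.12 ± 0.08) did not pass. Oligodendrocyte and myelin markers had 21 of 23 members higher (median 0.17, adjusted p = 0.164), with MBP, the myelin basic protein gene, at 9848 ± 4085 and 8498 ± 3498 CPM (0.22 ± 0.28). Oligodendrocyte precursor markers had 8 of 15 higher (adjusted p = 0.957; TNR -0.28 ± 0.11). Astrocyte and Bergmann glia markers had 12 of 16 lower (adjusted p = 0.256), with GFAP, the astrocyte filament gene, at 3817 ± 772 and 3707 ± 889 CPM (0.06 ± 0.13).

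Microglia and macrophage markers had 13 of 22 lower (adjusted p = 0.957), with AIF1 at 12.6 ± 2.3 and 11.5 ± 2.7 CPM (0.14 ± 0.13). Endothelial and blood-brain barrier markers (10 of 18 lower, adjusted p = 0.959; KDR -0.16 ± 0.08), pericyte and smooth muscle markers (9 of 15 higher, adjusted p = 0.782; RGS5 -0.25 ± 0.09) and meningeal and fibroblast markers (14 of 19 lower, adjusted p = 0.250; OGN -0.20 ± 0.08) did not pass. Choroid plexus and ependymal markers had 7 of 12 lower (adjusted p = 0.513; TRPM3 -0.22 ± 0.10). TTR, the transthyretin gene of the choroid plexus, was at 227 ± 441 and 191 ± 264 CPM (-0.05 ± 1.55), a log2 standard error larger than for the other genes named in advance that were tested.

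Of the stress and hormone lists, none passed camera. Glucocorticoid response genes had 11 of 16 higher (adjusted p = 0.179), and their score was higher by 0.09 (permutation p = 0.0384, adjusted p = 0.475), with PER1 at 0.33 ± 0.14 and ZBTB16 at 0.57 ± 0.27. The circadian clock list had 11 of 16 higher (adjusted p = 0.214; CRY2 0.22 ± 0.09). The clock score was 6.05 in BDL replicate 1, 6.01 in SHAM replicate 1 and 5.91 in BDL replicate 2, the earliest libraries deposited. It was 5.45, 5.50, 5.63 and 5.61 in BDL replicates 8, 9, 10 and 11, deposited late. PER1 was at 221, 185 and 202 CPM in those earliest libraries and at 108, 128, 158 and 125 in those late ones. SHAM replicates 8, 9, 10 and 11, also deposited late, had clock scores of 5.54, 5.57, 5.53 and 5.61. Their glucocorticoid scores were 4.79, 4.97, 4.92 and 4.87, against 4.79, 5.01, 4.90 and 4.97 in BDL replicates 8, 9, 10 and 11. Among these late libraries BDL and SHAM overlapped in both scores. The earliest libraries were mostly BDL, and order of deposition was not tested. It may account for part or all of the clock and glucocorticoid differences and is not excluded. HR was the 1 member of the thyroid hormone response list (7 of 12 higher, adjusted p = 0.908) that passed when adjusted over the list alone (p = 0.00552), and 0 passed over all genes. PFKFB3, a regulator of glycolysis, was likewise the 1 member of the hypoxia and glycolysis list to pass adjusted over the list alone (p = 0.0304; -0.28 ± 0.08; list 8 higher and 8 lower, adjusted p = 0.693). In each of the other 40 lists, 0 members passed adjusted over the list alone. That adjustment does not account for the 42 lists tried, so a few lists with a passing member can come from chance alone.

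The remaining lists gave camera adjusted p values above 0.05. They were cytosolic ribosomal proteins (23 of 26 higher, 0.0767; RPS20 0.10 ± 0.08), cytokine and NF-kappaB genes (10 of 14 higher, 0.179; SELP 0.60 ± 0.27), and ammonia, glutamate and astrocyte osmotic handling (11 of 16 lower, 0.250). Insulin, IGF and growth genes had 12 of 16 lower (0.309; EIF4EBP1 -0.22 ± 0.10), retinoid pathway genes 10 of 15 lower (0.513; CYP26B1, which degrades retinoic acid, -0.26 ± 0.09), and acute phase and reactive glia genes 10 of 15 higher (0.625; SERPINA1 0.23 ± 0.11). NRF2 and oxidative stress response genes had 12 of 18 higher (0.782; FTL 0.11 ± 0.08), and unfolded protein and integrated stress response genes split 9 and 9 (0.850; ASNS -0.19 ± 0.09). Nuclear-encoded respiratory chain genes had 16 of 31 lower (0.782; UQCRC2 -0.10 ± 0.06), mitochondrially encoded genes 9 of 12 lower (0.850; CYTB -0.06 ± 0.07), heat shock genes 8 of 13 lower (0.850; CHORDC1 -0.10 ± 0.05), and vitamin D, E and K handling genes 6 of 8 higher (0.941; VKORC1L1 -0.09 ± 0.05). Cell cycle genes split 11 and 11 (0.957; MCM6 -0.18 ± 0.08).

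Between the sexes, 9 genes passed, 8 higher in females and 1 lower. KDM6A, a histone demethylase gene that escapes X inactivation (X chromosome, 39953764 to 40154197 on Sscrofa11.1), was at 59.7 ± 5.8 CPM in 12 females and 43.1 ± 3.6 in 10 males (log2 fold change 0.49 ± 0.06, above the male mean in 12 of 12 females, edgeR adjusted p = 1.96e-05). TXLNG, also X-linked (13229680 to 13292371), was higher in females by 0.44 ± 0.08 (12 of 12, adjusted p = 0.0162; 0.0531 without BDL replicate 7). HR, on chromosome 14 (6386900 to 6404968), was higher in females by 0.56 ± 0.11 (41.8 ± 7.3 and 30.4 ± 8.6 CPM, 12 of 12, adjusted p = 0.0275). The adjusted p of HR was 0.0675 without BDL replicate 5, 0.0965 without BDL replicate 6, 0.0830 without BDL replicate 7, 0.0720 without BDL replicate 11, 0.0548 without SHAM replicate 3 and 0.412 with no treatment term. BDL replicates 5, 6, 7 and 11 are the 4 BDL males, at 19.6 to 25.6 CPM of HR, which lower the male mean. The SHAM males were at 25.7 to 45.9 CPM and the females at 31.7 to 53.9, so these overlapped. The HR call between the sexes is thus not separate from the low HR of BDL males given below. The other 6 genes have no symbol in the table used here, and 2 of them had 700 or more counts in each female and at most 4 in each male. The count filter asks for a gene in 11 libraries while there are 10 males, so most male-specific genes were not tested: without the filter 31 genes passed, 22 of them lower in females, of which 19 had been untested. Leaving out any of the 12 females gave between 21 and 26 genes, and leaving out any of the 10 males between 7 and 11. limma-voom called 13, and DESeq2 called 43 without the count filter and 23 on the filtered genes.

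The interaction asks whether BDL acted differently in the sexes, and 0 genes passed edgeR's test (689 at an unadjusted p under 0.05; limma-voom 0 and 1320, DESeq2 on the filtered genes 0 and 736). The smallest p belonged to SQOR, which oxidises sulfide in mitochondria (difference female minus male 0.54 ± 0.13), RNF144A (-0.54 ± 0.13), MAP6D1 (-0.42 ± 0.10) and NTS, the neurotensin gene (-2.23 ± 0.56), each with an adjusted p of 0.917. Within females (7 BDL, 5 SHAM) 0 genes passed (874 at an unadjusted p under 0.05; limma-voom 0 and 1147, DESeq2 on the filtered genes 0 and 928). RNF144A was at -0.40 ± 0.09, YPEL4 at 0.48 ± 0.11, TTLL11 at -0.41 ± 0.11 and P3H1 at 0.26 ± 0.07, each with an edgeR adjusted p of 0.795. No list score differed in its response between the sexes (smallest permutation p = 0.0375, phospholipid synthesis and remodelling; adjusted p = 0.527).

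Within males (4 BDL, 6 SHAM) TPD52L1 was at 5.36 ± 0.46 CPM in BDL and 2.74 ± 0.61 in SHAM animals (log2 fold change 0.97 ± 0.18), and the lowest BDL male, at 4.93, stood above the highest SHAM male, at 3.85. The groups of males did not overlap for 102 of 14994 genes, where chance gives 143 (0.952%), and HR was another of them. In the same BDL males the difference in the myelin score was 0.52, with 4 of 4 above the SHAM mean (within-male permutation p = 0.0864). It was 0.16 for oligodendrocyte precursor markers (4 of 4 above, permutation p = 0.135) and 0.24 for microglia markers (4 of 4 above, permutation p = 0.186). The difference in the choroid plexus score was -0.62, with 4 of 4 below (permutation p = 0.156). In females the differences had the opposite sign, at -0.20 for myelin, -0.14 for oligodendrocyte precursor, -0.21 for microglia and 0.24 for choroid plexus markers. HR was at 22.6 ± 3.2 CPM in BDL and 35.7 ± 6.6 in SHAM males (-0.66 ± 0.15), SQOR was at -0.42 ± 0.10 and RUSF1 at 0.47 ± 0.12. In females the same fit put TPD52L1 at 0.38 ± 0.18 and HR at -0.23 ± 0.13. The difference between the sexes had an adjusted p of 0.917 for both (unadjusted 0.0312 and 0.0364). edgeR called 0 genes within males (612 at an unadjusted p under 0.05; TPD52L1 adjusted p = 0.295) and limma-voom 0 (1335). Without the count filter DESeq2 called 2 of 25710 genes (821 at an unadjusted p under 0.05): TPD52L1 (adjusted p = 0.00382) and TRDN, the triadin gene (2.73 ± 0.56, adjusted p = 0.0138), which did not pass the count filter and is named after its value was seen. On the filtered genes it called 1, TPD52L1 (adjusted p = 0.00412; 660 at an unadjusted p under 0.05).

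**Figure D3:**
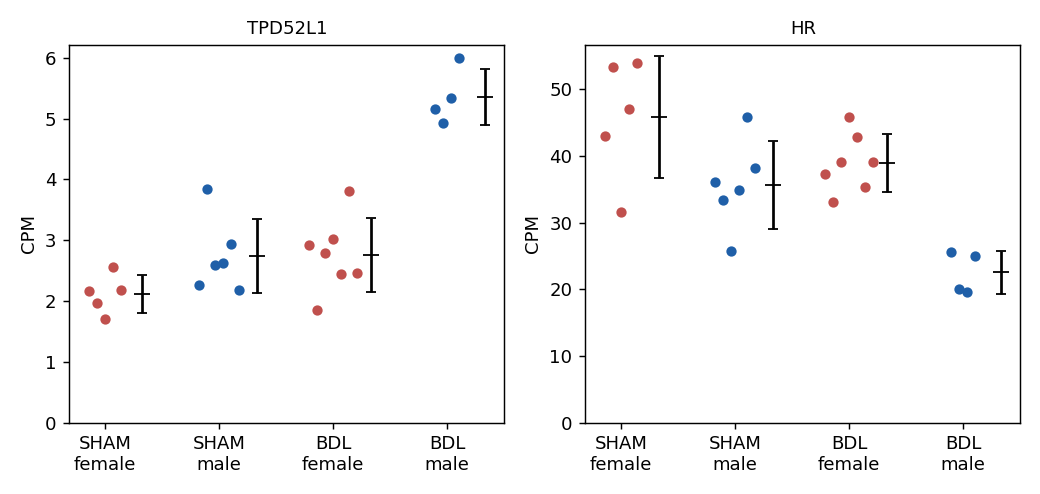
CPM of TPD52L1 and HR in each animal (points) by treatment and sex, with the group mean ± SD (bars; n = 5, 6, 7 and 4 from left to right). The lowest of the 4 BDL males is at 4.93 CPM of TPD52L1 and the highest of the 6 SHAM males at 3.85.

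Body weight was tested beside sex and treatment. The genes with the smallest p all had higher levels in heavier animals: ARHGAP30 (log2 0.43 ± 0.08 per SD of weight), GRIN3A, an NMDA receptor subunit (0.18 ± 0.04), LCP1, the leukocyte plastin gene (0.27 ± 0.06), and P2RY12, the microglial ADP receptor (0.27 ± 0.06), each with an edgeR adjusted p of 0.335. edgeR called 0 genes (1108 at an unadjusted p under 0.05) and limma-voom 0 (1397). Without SHAM replicate 1 it called 9 genes, all higher with weight and among them P2RY12, LCP1, ARHGAP30 and GRIN3A (adjusted p = 0.0458 each). Without BDL replicate 4 it called 3, of which TAP1, an antigen peptide transporter gene, has a symbol (0.39 ± 0.07, adjusted p = 0.0421, named after its value was seen). Camera with the preset correlation called the following lists with weight, and each call was lost with an estimated correlation. Microglia and macrophage markers were higher in heavier animals for 22 of 22 members (median 0.16 per SD, camera adjusted p = 1.86e-08, against p = 0.0447 and adjusted p = 0.529 with an estimated correlation), with 6 members passing adjusted over the list alone and 0 over all genes. Interferon response genes were higher for 26 of 26 (median 0.31, camera adjusted p = 8.83e-18, against p = 0.0287 and adjusted p = 0.529 with an estimated correlation), with 0 passing adjusted over the list alone and 0 over all genes. Of the other lists called, astrocyte and Bergmann glia markers were higher in heavier animals for 15 of 16 members, with a camera adjusted p of 5.09e-04 and an adjusted p of 0.529 with an estimated correlation. Immediate early genes were higher for 15 of 17 members (adjusted p = 0.00277, and 0.573 with an estimated correlation). Endothelial markers were higher for 16 of 18 (adjusted p = 0.0214 and 0.573 in the same order). Cytokine and NF-kappaB genes were higher for 12 of 14 (0.0333 and 0.529) and oligodendrocyte precursor markers for 13 of 15 (0.0445 and 0.684). Interneuron markers (0.0467 and 0.591) and ammonia, glutamate and osmotic handling genes (0.0467 and 0.544) were each higher for 12 of 16. Choroid plexus and ependymal markers were lower, with 2 of 12 members on the higher side (0.00593 and 0.529). Granule neuron markers were lower, with 5 of 18 on the higher side (0.0333 and 0.573).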

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

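The fits with choroid plexus, meningeal and myelin scores as covariates, and those without the animal of each group with the lowest myelin score, and DESeq2 on the genes of the count filter, were chosen after seeing the data. The count of 0 genes for BDL against SHAM kept under 13 of 15 alternatives and in each of 22 fits without 1 animal (0 to 0); DESeq2 called 1 with and without the count filter. Within males DESeq2 called 2 without the filter and 1 with it. The interaction and the within-female count stayed at 0 throughout (0 to 0 without 1 animal, as within males). The body weight count was 0 in 6 of 6 alternatives and 0 to 9 without 1 animal. For females against males, 9 genes became 31 with no filter, 23 with DESeq2 on the filtered genes and 43 with DESeq2 and no filter, and 7 to 26 without 1 animal: 21 to 26 when a female was left out and 7 to 11 when a male was, since without 1 animal the filter asks for 10 libraries, which the 10 males reach only when a female is the one left out. The camera count of 3 lists became 0 with an estimated correlation, 0 with fry, 6 with the choroid, meningeal and myelin scores as covariates, 7 without BDL replicate 2 and SHAM replicate 1, and 1 to 7 without 1 animal. Apart from the correlation the cause was not tested. The score test kept 0 of 42 lists with medians and with standardised members. The body weight difference was 9.09 in BDL minus SHAM and -29.6 within sex, both far inside the spread. Over 117 named genes and 36 settings, 4179 of 4207 values moved by at most 1 standard error, 26 moved further and 2, TPD52L1 with DESeq2 with and without the filter, passed the threshold. Since the main fit called none of these genes, it had no call that could be lost or reversed. At this depth and spread, changes of 1.25-fold were recovered in 45.1% of simulated cases, in runs where many genes were changed. Small changes can thus be missed, and more so where few genes change.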

Other observations

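Both tests of body weight on the interferon genes, the tests of TPD52L1 and the search for genes with separate low and high animals were chosen after results had been seen. Some genes had separate low and high animals. With a gap of at least 1.5 log2 units and at least 3 libraries on each side, 17 of 14994 genes met that description, of which 3 followed sex and 6 have a symbol. FGF10, a fibroblast growth factor gene, had 121 to 173 counts in 9 libraries (5 BDL, 4 SHAM) and 0 to 16 in the other 13. SLC4A5, a bicarbonate transporter gene of the choroid plexus, had 258 to 449 counts in 12 libraries (5 BDL, 7 SHAM) and 37 to 86 in 10. CXCL9, an interferon-gamma-induced chemokine gene, was high in 8 BDL and 4 SHAM animals, and LIPM, KRT80 and IL21R were the others with a symbol. A two-sided Fisher's exact test against treatment gave a smallest p of 0.0635 over the 17 genes (adjusted 1), for a gene without a symbol that was high in 5 BDL and 10 SHAM animals. No genotype was tested.

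With treatment labels regrouped within sex, the real count of 0 genes is reached by 100 of 100 splits by construction for BDL against SHAM (highest other 121), within females (highest other 30), within males (highest other 2) and for the interaction (highest other 1), so these counts test nothing about chance. For BDL against SHAM 7 of the other splits made any call, and the one with 121 may reflect a structure among the animals, which was not tested. Camera called at least the real 3 lists in 93 of 100 splits (median of the others 8, highest 23). The real count was thus below the median under regrouping, so chance is not excluded and the count is no support for an effect of BDL. With sex labels regrouped within treatment, 2 of 100 splits gave at least the real 9 genes, the real one included. A count of this size was thus rare, but not absent, under regrouping. Of the other splits 4 made any call, and the highest, 746, may reflect a structure of the samples, which was not tested.

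The interferon genes stood higher in BDL but varied widely in both groups. In 14 of 100 splits the list had a camera p as small as the real 8.68e-10 (smallest other 1.04e-30), so chance is not excluded. With the microglia and blood cell scores as covariates the BDL minus SHAM difference of the score went from 0.41 to 0.14. The microglia score itself differed by only -0.0079 between the groups (permutation p within sex = 0.949) and the blood cell score by 0.37. The fall thus went with the blood cell score, and blood cells may account for part of the difference. Its distance from the midpoint between 0 and 0.41 was -0.06 with a jackknife error of 0.22, so the explanations cannot be told apart. With body weight as a covariate the difference was 0.45, above that midpoint by 0.24 with an error of 0.14. Weight thus accounted for -0.0367 of the difference, opposite in sign to what heavier BDL animals would give, but with a jackknife error of 0.156 this was not 2 errors from the midpoint, so neither weight nor an effect of BDL is excluded.

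The immediate early genes had a camera p as small as the real 1.83e-04 in 18 of 100 splits (smallest other 1.32e-18), and the synapse genes one as small as the real 0.00203 in 5 of 100 (smallest other 2.35e-04), so chance is not excluded for either. The immediate early score difference was 0.24, and 0.21 with library depth and the share of reads given to no gene as covariates, above the midpoint between 0 and 0.24 by 0.09 with an error of 0.10.

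TPD52L1 in BDL males was picked out after its values were seen, and a higher level there is a hypothesis. In 12 of 100 splits some gene reached a p within males as small as its 1.96e-05 (smallest other 1.30e-10), so a leading gene of this size could come from chance. Over both sexes 39 of 100 splits reached a p as small as its 5.48e-05 (smallest other 1.04e-07). With the choroid plexus, meningeal, myelin and microglia scores as covariates, the log2 CPM difference in males went from 0.96 to 0.77, above the midpoint between 0 and 0.96 by 0.29 with a jackknife error of 0.21, so another mix of cell types stays open there. Over both sexes, where these scores differ less between the groups, it was 0.62 without and 0.56 with the first 3 scores, above the midpoint between 0 and 0.62 by 0.24 with an error of 0.08. The gene had 29 to 103 counts per library, and over 36 alternatives for both sexes its adjusted p ran from 0.0398 to 1.

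Heavier animals may carry more transcripts of microglia and of the interferon response, though no correlation of a score with weight passed adjustment over 42 lists, nor did camera with an estimated correlation. The interferon score had r = 0.55 with weight (permutation p = 0.00877, adjusted 0.368; rho = 0.52, p = 0.0146, adjusted 0.396), 0.46 within BDL and 0.73 within SHAM, 0.41 in females and 0.67 in males, and r = 0.45 without the 2 animals farthest from the median weight (p = 0.0457). The microglia score had r = 0.37 (p = 0.0914, adjusted 0.548; rho = 0.34, p = 0.127, adjusted 0.593), 0.18 within BDL and 0.58 within SHAM, 0.69 in females and 0.19 in males. The immediate early gene score had r = 0.43 (p = 0.0480, adjusted 0.505) and rho = 0.48 (p = 0.0250, adjusted 0.396), with r = 0.34 and p = 0.143 without those 2 animals, 0.53 in females and 0.09 in males. The cytokine score had r = 0.45 (p = 0.0385, adjusted 0.505) and rho = 0.45 (p = 0.0354, adjusted 0.396), with r = 0.46 and p = 0.0425 without them, 0.27 in females and 0.61 in males. Whether these values differ between the sexes was not tested. Without those 2 animals the microglia score had r = 0.20 and p = 0.386. The prediction written beforehand would count that as resting on them, but since p was above 0.05 with all 22 animals too, it was read, after the value was seen, as deciding nothing. The microglia slope of 0.143 per SD of weight was 0.135 with library depth and the share of reads given to no gene as covariates and 0.133 with the blood cell score, above the midpoint between 0 and 0.143 by 0.06 in both cases with errors of 0.06 and 0.04, so neither is excluded.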
